A study of Homo sapiens and Mus musculus with 26 samples.

How the data were processed

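MHCC97H cells were profiled by sequencing of input RNA and of polyribosome-associated mRNA in control and METTL1 knockdown cells, 3 libraries in each of 4 groups. TRAC-Seq libraries of AlkB-treated small RNA, with and without NaBH4, came from liver tumors of 3 control mice and from SNU449 cells with and without METTL1 overexpression. Groups and repeat numbers were taken from the sample titles. Nothing in the labels says that the repeats of the cell line came from separate cultures, so p-values measure the spread between these samples, which may be technical. The MHCC97H TRAC-Seq libraries were not analysed here.

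The authors deposited FPKM values per gene for the 12 MHCC97H libraries. The table holds 8074 genes, none below an FPKM of 1 in any library, so genes that fell below that level in any library are not seen. Bowtie2, HTSeq and GRCh38 are named in the submitters' processing notes without versions or roles, and GRCh38 is named on the mouse samples too. The mouse build, the annotation and the normalization steps are not given in the sources used here. The deposited TRAC-Seq tables are named RPKM, but their values behave as a signal per feature that the authors obtained by dividing read counts by 1 factor per library: with the smallest value of each library as the worth of 1 read, 99.99% of mouse and 99.98% of SNU449 values were whole within a tolerance of 0.01, for features of any length. They were therefore treated as scaled counts per feature, not as values per kilobase, and the design written before the data were examined assumed RPKM. Mature tRNA reads per library numbered 1943810 to 3368950. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Those of the SNU449 list medians came from 1000 Poisson draws that treated isodecoders as independent, which those with near-identical sequence are not. Some medians lay near an end of their interval, so these intervals are only a rough guide.

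FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using group means over all 12 libraries, empirical Bayes moderation with an intensity trend and Benjamini-Hochberg adjustment, two-sided, called at an adjusted p of 0.05. The planned filter of FPKM of at least 1 in at least 3 libraries removed 0 genes. Fold changes on this scale understate the change of low genes. Translation efficiency was the interaction of knockdown and library kind in the same model. Of 35 gene lists fixed before the data were examined, 26 had at least 5 listed members and were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and with fry. The other 9 lists were not tested: markers of endothelial cells and fibroblasts, mitochondrially encoded mRNAs, noncoding nuclear RNAs and replication-dependent histones had 0 listed members, METTL1 with WDR4 and leukocyte markers 2, other epithelial markers 3 and aminoacyl-tRNA synthetases 4. A planned test of codons read by m7G tRNAs was not run, since no coding sequences were used here. Genes with near-identical copies, such as ribosomal protein genes and SPANXC, are uncertain where counting split reads between copies. Gene positions and genomic spans came from a reference gene table of the GRCh38 assembly, and 98.7% of the genes had a span.

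The genes named were METTL1, WDR4, CCNA2, EGFR and VEGFA, the 8 largest rises and falls among genes past the threshold with a mean FPKM of at least 5 and no overlap between groups or, where none passed, the 5 with the smallest p, and from each list the members with the smallest p, 3 where the list passed or had at least 3 called members and otherwise at most 2. A gene outside this rule is said to be picked after its values were seen. Results of some genes are not reported here. Applying the same rule to the fit of the 6 polysome libraries, and naming members of lists with at least 3 calls there, was decided after that fit's result was seen. Same-numbered libraries deviated together from their group means, with a lowest correlation across genes of 0.319 in MHCC97H and of 0.233 in the mice, where the number is the animal. In MHCC97H repeat 1 stood apart from repeats 2 and 3, which can give such correlations without a pairing of repeats 2 and 3. Deviations of libraries with different numbers were not compared. Repeats 2 and 3 of each group were close, with identical values in 0.0743% to 0.669% of genes. Whether they differed by more than sampling noise was not tested, since the table gives no depth. Gene counts are therefore given both with these repeats separate and with them averaged as 1 sample.

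Mouse features with a value of at least 1 in at least 3 of 6 libraries (16849 of 19077) were tested with limma on log2(value + 1), NaBH4-treated against input. As an added alternative, the recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16. For list medians, 3' fragments with a mean value of at least 10 were used. SNU449 libraries had no replicates, so list medians were set against 10000 random lists matched on level. These were drawn from all 227 isodecoders used, of which 147 were in the m7G list. Random lists therefore shared many members with that list, and percentiles of different lists are not independent. The microRNA names of the let-7 list were matched with the prefix used in the table, and 2 repeated feature names were kept apart.

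Both tests were tried on simulated data. For the polysome comparison with 8074 genes, 100 genes changed by a log2 of 1 and 100 by 2 were recovered to 19% and 61% over all 12 libraries with 13 false calls, and to 57% and 92% over the polysome libraries alone with 10 false calls. For the mouse comparison with 16849 features, 0%, 7% and 56% of 100 features changed by a log2 of 1, 2 and 4 were recovered, with 4 false calls, and the size of 4 was added after the smaller sizes gave few recoveries. The low recovery limits what the absence of a call says. Simulated libraries of the polysome comparison were drawn independently, whereas some real repeats of a group were much closer to each other than to the rest. How this closeness changes recovery and false calls was not tested. The simulated values therefore do not give the error of the calls made over the real polysome libraries alone. Alternatives covered the pseudocount (0.1), filters on low values, scaling, the intensity trend, the libraries in the fit, the repeat number as a block and leaving out each library, and those added later are named as such in the closing section.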

Results

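The series follows METTL1, the catalytic subunit of the methyltransferase that places N7-methylguanosine (m7G) on a subset of tRNAs, in liver cancer. MHCC97H and SNU449 are human hepatocellular carcinoma cell lines. In MHCC97H cells, mRNA bound to polyribosomes and the input RNA were sequenced after knockdown of METTL1 by a short hairpin RNA and in control (NC) cells, with 3 libraries in each of the 4 groups. The stated purpose was to find genes whose translation differed between knockdown and control cells. TRAC-Seq, in which NaBH4 treatment leads to cleavage of tRNA at m7G and so to 3' tRNA fragments in small RNA libraries, was applied to liver tumors of 3 control mice and to SNU449 cells with and without METTL1 overexpression, each with an untreated input. The 12 MHCC97H libraries listed 8074 genes, all with an FPKM of at least 1 in every library, and their FPKM summed to between 482334 and 821900. The FPKM table gives no read depth, so no counting error can be attached to its values. The reads recovered for mature tRNA fragments ranged from 1943810 to 2820880 per mouse library and from 2222880 to 3368950 per SNU449 library.

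METTL1 was lower in every knockdown library than in every control library. In input RNA it was at 41.1 ± 6.15 FPKM in control cells and 15.2 ± 3.23 FPKM in knockdown cells (SD, n = 3 each), and in polysome RNA at 42.4 ± 3.75 and 18.9 ± 9.30 FPKM. The polysome value of the knockdown libraries was 8.29 FPKM in repeat 1 and 22.9 and 25.6 FPKM in repeats 2 and 3. METTL1 lies on chromosome 12 from 57768471 to 57772105 (GRCh38). WDR4, the partner protein of METTL1 in the methyltransferase, was at 16.6 ± 0.838 FPKM in control polysome RNA and 18.2 ± 0.384 FPKM in knockdown polysome RNA (SD, n = 3 each). Fitted over all 12 libraries, the log2 difference of METTL1 in polysome RNA was -1.26 with a standard error of 0.36 and a limma adjusted p of 0.602, so it did not pass the test although no library overlapped.

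Polysome-bound mRNA of EGFR, the receptor of epidermal growth factor, was at 8.27 ± 0.419 FPKM in control cells and 3.30 ± 0.186 FPKM in knockdown cells (SD, n = 3 each). Its log2 difference was -1.10, -1.10 and -1.12 in the 3 repeats, whereas its input RNA differed by -0.28 on average. Polysome-bound CCNA2, a cyclin of S phase and mitosis, was at 27.5 ± 5.17 FPKM in control and 16.5 ± 2.31 FPKM in knockdown cells. VEGFA, an angiogenic growth factor, was at 11.2 ± 0.818 and 8.38 ± 3.25 FPKM, and in repeat 1 it was 12.2 and 12.1 FPKM. AZGP1, a secreted glycoprotein, went the other way, from 1.80 ± 0.235 to 9.48 ± 2.23 FPKM. EGFR lies on chromosome 7 from 55019017 to 55211628, CCNA2 on chromosome 4 from 121816444 to 121823883, VEGFA on chromosome 6 from 43770211 to 43786487 and AZGP1 on chromosome 7 from 99966730 to 99976031 (GRCh38).

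**Figure D1:**
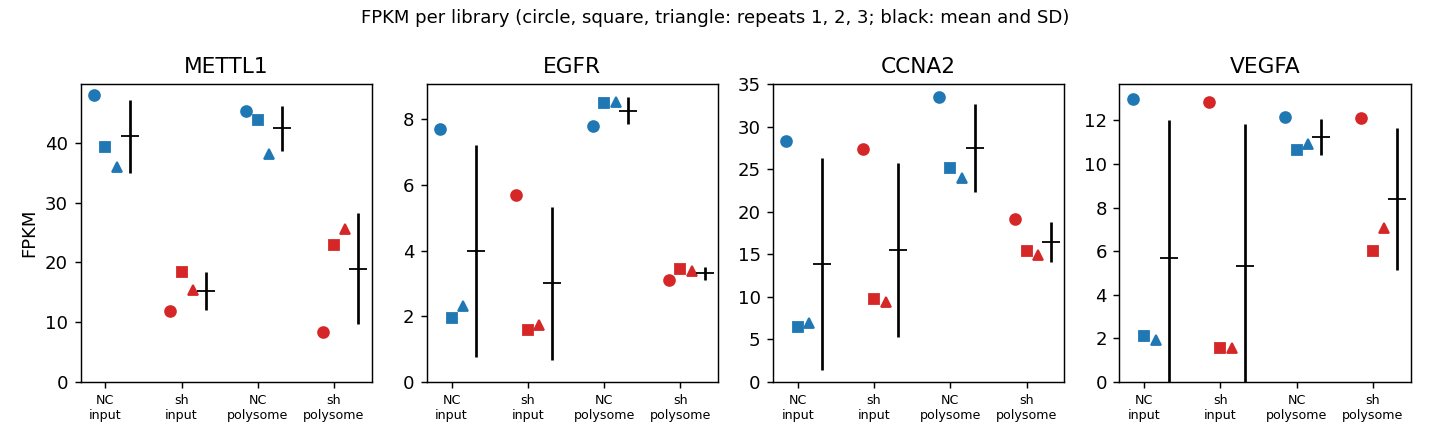
FPKM of METTL1, EGFR, CCNA2 and VEGFA in each MHCC97H library; circles, squares and triangles are repeats 1, 2 and 3, blue is control, red is knockdown, and black bars give the mean and SD of 3 libraries. EGFR in polysome RNA lay between 7.79 and 8.53 FPKM in control and between 3.09 and 3.43 FPKM in knockdown libraries, while in the input RNA of EGFR, CCNA2 and VEGFA repeat 1 lay above repeats 2 and 3.

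ACY3 and AZGP1 had higher polysome-bound mRNA in every knockdown library, and POLR3B, DHX29 and PAK1IP1 lower. These 5 genes had the smallest p over all 12 libraries. With all 12 libraries in one limma fit, 0 of 8074 genes passed an adjusted p of 0.05 in the polysome comparison, and 609 had an unadjusted p below 0.05. With only the 6 polysome libraries in the fit, an alternative fixed before the data were examined, limma called 1117 genes, 88 higher and 1029 lower in knockdown cells. Lower calls made up 92.1% there, 66.6% with quantile normalization of the same libraries (902 calls) and 66.5% with the repeat number as a block (3392 calls). Groups did not overlap in 40.2% of the genes, 1106 higher and 2141 lower, where chance gives 10% if the libraries of a group are independent. Repeats 2 and 3 were close and repeat 1 stood apart, so 10% is not the value without a change here or below. The input libraries of repeat 1 stood apart from those of repeats 2 and 3: the SD of the log2 difference over genes was 1.20 between repeats 1 and 2 of control input RNA and 0.126 between repeats 2 and 3. Repeats 2 and 3 of control polysome RNA differed by an SD of 0.106, and of knockdown polysome RNA by 0.143. When repeats 2 and 3 were averaged as 1 sample, limma called 0 genes both over all libraries and over the polysome libraries alone, with 72 and 1175 genes at an unadjusted p below 0.05. With the repeat number as a block in the fit over all libraries, 1 gene passed, AZGP1, with an adjusted p of 0.00891. Without control input replicate 1, limma called 4 genes, ACY3 (adjusted p = 0.0408) and AZGP1 (0.0486) higher and DHX29 (0.0408) and CDC5L (0.0448) lower, of which CDC5L was picked only after its value was seen.

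In the fit of the 6 polysome libraries, the largest rises were found for TUBB6, a tubulin, by 2.10 on the log2 scale (limma adjusted p = 0.0394), for AZGP1 by 1.88 (adjusted p = 0.00737), and for the secreted liver proteins AMBP by 1.39 (adjusted p = 0.0112) and HABP2 by 1.34 (adjusted p = 0.00737). AMBP was at 3.08 ± 0.296 FPKM in control and 9.89 ± 2.72 FPKM in knockdown polysome RNA, and HABP2 at 3.82 ± 0.340 and 11.2 ± 0.387 FPKM (SD, n = 3 each). The other genes with the largest rises were POU2AF1, a transcriptional coactivator, SPANXC, a cancer-testis antigen with near-identical copies, PSMB9, a subunit of the immunoproteasome, and PRODH2, a proline dehydrogenase family member, with log2 differences from 0.98 to 1.05. The largest falls were those of ADAM9, a membrane metalloprotease, at -2.12 (limma adjusted p = 0.00760) and TFAM, which packages mitochondrial DNA, at -2.004 (adjusted p = 0.00737). NFE2L2, a transcription factor of the oxidative stress response, fell by 1.81, HIF1A, the oxygen-regulated transcription factor, fell by 1.72, and the chaperones HSP90B1 and HSPH1 fell by 1.69 and 1.63. B4GALT4, a galactosyltransferase, and PBDC1 differed by -1.87 and -1.86. HIF1A was at 23.5 ± 2.29 FPKM in control and 6.42 ± 0.420 FPKM in knockdown polysome RNA, and TFAM at 15.5 ± 2.83 and 3.10 ± 0.433 FPKM. HIF1A lies on chromosome 14 from 61695513 to 61748258 and TFAM on chromosome 10 from 58385410 to 58399220 (GRCh38). EGFR and CCNA2 passed in this fit, with limma adjusted p of 0.00737 and 0.0441 and log2 differences of -1.11 and -0.70, while METTL1 (0.0765), WDR4 (0.484) and VEGFA (0.264) did not. Without the trend on genomic span, a test chosen after the data were seen, EGFR was at -0.74 (limma adjusted p = 0.0281) and CCNA2 at -0.81 (0.0487), and without the trends on span and level at -0.71 (0.0303) and -0.75 (0.0454). Over all 12 libraries the smallest p belonged to ACY3, an aminoacylase, at 1.28 (limma adjusted p = 0.0956), followed by AZGP1 (0.218), POLR3B of RNA polymerase III (0.430), the initiation helicase DHX29 (0.469) and the ribosome biogenesis factor PAK1IP1 (0.549). The difference in polysome RNA followed genomic span, with a Spearman correlation of -0.455 over 7972 genes between the log2 difference and the span. Genes are not independent replicates, and transcript length was not examined.

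Transcripts of cytosolic ribosomal proteins were higher as a group in polysome RNA of knockdown cells, with a median log2 difference of 0.42 over 77 members, of which 75 were above 0, although none passed as a single gene. Transcripts of nuclear-encoded subunits of oxidative phosphorylation were also higher, with a median of 0.29 over 75 members, and DNA repair transcripts were lower, with a median of -0.46 over 21 members. The medians in repeats 1, 2 and 3 were 0.18, 0.58 and 0.54 for ribosomal proteins, 0.15, 0.36 and 0.37 for oxidative phosphorylation and -0.68, -0.30 and -0.35 for DNA repair. In a test chosen after the data were seen, the medians were 0.25, 0.22 and -0.16 without the trend on genomic span and 0.04, 0.08 and -0.16 without the trends on span and level. The limma camera test with a preset correlation gave adjusted p of 8.93e-05, 0.00509 and 0.0177 for these lists. With an estimated correlation the p were 0.290, 0.244 and 0.212, and none of the 26 lists tested passed. At the preset correlation, 8 of 10 splits of the same libraries, the real one among them, gave at least as many passing lists. No member of these lists passed in limma over all 12 libraries, over all genes or adjusted over the list alone (0 of 77, 0 of 75 and 0 of 21). In the fit of the polysome libraries alone, 0 ribosomal protein genes and 2 higher (COX5B and NDUFA3) and 2 lower (NDUFS1 and SDHD) oxidative phosphorylation genes passed over all genes in limma, and 0 and 0 adjusted over the list alone. These 4 genes were picked after their values were seen. Of the 21 DNA repair genes, 6 fell there in limma adjusted over the list alone, among them MSH6, which also passed over all genes (adjusted p = 0.0183). RPL38, RPL37A and RPL39 of the ribosome differed by 0.45, 0.62 and 0.38, NDUFA4, NDUFA7 and COX8A of the respiratory chain by 0.36, 0.61 and 0.57, and the repair genes MSH6, PRKDC and RBBP8 by -1.01, -0.89 and -1.10. With the repeat number as a block, the call of the DNA repair list ended (limma camera adjusted p = 0.0713), as it did over the polysome libraries alone (0.0886), a list test chosen after the data were seen, and with quantile normalization those of the ribosomal protein (0.228) and oxidative phosphorylation (0.405) lists ended. The list of G2 and M phase genes had a median of -0.40 over 31 members and did not pass (limma camera adjusted p = 0.106, and p = 0.352 with an estimated correlation), with KIF11 at -1.08 and ECT2, which passed in the fit of the polysome libraries (limma adjusted p = 0.00737), at -1.62. It passed, lower, among genes with a mean FPKM of at least 5 (limma camera adjusted p = 0.0352), with quantile normalization (0.0113) and, in a test chosen after the data were seen, with repeats 2 and 3 averaged (0.0298). Shifting each library to an equal median moved all polysome differences by 0.17.

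In input RNA, AZGP1 was higher and METTL1 lower in every knockdown library than in every control library. The level of AZGP1 was 2.48 ± 0.927 FPKM in control and 10.02 ± 3.04 FPKM in knockdown cells (SD, n = 3 each), a log2 difference of 1.66. The laminin chain LAMA5, the endosomal protein ZFYVE28 and the ligand WNT7B had differences of -0.76, -0.46 and -1.07, and ACY3 of 0.70, each with the same sign in all 3 repeats. None of 8074 genes passed in limma over all 12 libraries (0 calls, 134 with an unadjusted p below 0.05), nor in the fit of the 6 input libraries (0 calls, 44 with an unadjusted p below 0.05). METTL1 had a log2 difference of -1.39 with a standard error of 0.36 and a limma adjusted p of 1.00. Groups did not overlap in 4.32% of the genes, where chance gives 10%. With the repeat number as a block 1 gene passed, AZGP1, with a limma adjusted p of 0.0248. With repeats 2 and 3 averaged as 1 sample, limma called 0 genes, with 3 at an unadjusted p below 0.05. Over the input libraries alone, so averaged, it called 0, with 2. The differences of EGFR (-0.28), VEGFA (-0.17), CCNA2 (0.29) and WDR4 (-0.28) did not pass in limma. In repeats 1, 2 and 3 EGFR was at -0.38, -0.19 and -0.28, VEGFA at -0.01, -0.29 and -0.20, CCNA2 at -0.05, 0.54 and 0.39 and WDR4 at -0.67, 0.03 and -0.18, so EGFR and VEGFA were lower in all 3 repeats. Each average changed sign when 1 library was left out, which leaves its pair incomplete. EGFR was at 0.21 and VEGFA at 0.57 without control input replicate 1, and CCNA2 was at -0.18 and WDR4 at 0.10 without knockdown input replicate 1. VEGFA was also at 0.24 without knockdown input replicate 2 or 3, and CCNA2 at -0.05 without control input replicate 2 and -0.01 without control input replicate 3.

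Glycolysis transcripts were lower as a group in input RNA of knockdown cells, with a median log2 difference of -0.22 over 19 members, 18 of them below 0. The median was -0.05 in repeat 1, whose input libraries stood apart, and -0.35 and -0.33 in repeats 2 and 3. PFKP, ALDOA and GPI, enzymes of that pathway, differed by -0.40, -0.43 and -0.24. The limma camera test gave an adjusted p of 0.00122 with the preset correlation, and with an estimated correlation the p was 0.00390 and the adjusted p 0.101. Cytosolic ribosomal protein transcripts were higher, with a median of 0.17, and of 0.17, 0.14 and 0.19 in the repeats (limma camera adjusted p = 0.0357, and p = 0.486 with an estimated correlation), and RPS27A, RPS6 and RPSA differed by 0.51, 0.18 and 0.31. Of 10 splits of the same libraries, the real one among them, 9 gave at least as many passing lists at the preset correlation. No member of either list passed in limma over all genes or adjusted over the list alone (0 of 19 and 0 of 77). With quantile normalization the call of the ribosomal protein list ended (limma camera adjusted p = 0.364), and RPSA was at -0.02 without control input replicate 1. With the repeat number as a block a further list passed, that of the oxidative stress response, which was lower (limma camera adjusted p = 0.00667), while without the block its p with an estimated correlation was 0.0788.

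Translation efficiency, the polysome difference minus the input difference, was lowest relative to its error for PAK1IP1 at -1.69 with a standard error of 0.30, for TRMT10C, a methyltransferase subunit of mitochondrial RNase P, at -1.83 with a standard error of 0.33, and for DHX29 at -1.42, the recombination factor RAD51AP1 at -1.91 and the proteasome subunit PSMA4 at -1.44. Each was below 0 in all 3 repeats and none passed, with a limma adjusted p of 0.841 for all 5. CCNA2 was at -0.996, EGFR at -0.82 and VEGFA at -0.27, and METTL1 and WDR4 were at 0.13 and 0.41. Over all 12 libraries limma called 0 of 8074 genes, with 336 at an unadjusted p below 0.05, and 0 with the repeat number as a block, with 702. The polysome minus input differences of the 3 knockdown repeats did not overlap those of the 3 control repeats in 16.7% of the genes, 856 higher and 491 lower, where chance gives 10%. In repeats 1, 2 and 3 METTL1 was at -0.39, 0.15 and 0.62 and VEGFA at 0.0047, -0.44 and -0.37. With a pair left incomplete, METTL1 changed sign without knockdown input replicate 1 (-0.03) and without knockdown polysome replicate 2 (-0.08) or 3 (-0.15). VEGFA did so without knockdown input replicate 1 (0.55) and without control input replicate 2 (0.08) or 3 (0.13), and with quantile normalization (0.05). Without control input replicate 1, 3 genes passed in limma, CDC5L (adjusted p = 0.0134), DHX29 (0.0333) and RAD51AP1 (0.0384), and without knockdown input replicate 1 only PAK1IP1 passed (0.0493). A term for repeat 1 per library kind, added after the data were seen, gave 3434 calls, 1255 higher and 2179 lower. There CCNA2 (limma adjusted p = 0.000540) and EGFR (0.000443) passed. Where repeats 2 and 3 share a preparation, as their closeness leaves open, the spread in this fit and these p are too small. With repeats 2 and 3 averaged as 1 sample, also added later, limma called 0 genes, with 17 at an unadjusted p below 0.05. Shifting each library to an equal median moved all translation efficiency differences by 0.14.

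Transcripts of oxidative phosphorylation and glycolysis were higher in translation efficiency as groups, with medians of 0.37 over 75 members and 0.31 over 19 members, and DNA repair transcripts were lower, with a median of -0.38 over 21 members. The medians in repeats 1, 2 and 3 were 0.01, 0.56 and 0.50 for oxidative phosphorylation, 0.20, 0.31 and 0.38 for glycolysis and -0.63, -0.20 and -0.15 for DNA repair. The limma camera adjusted p were 0.00863, 0.00870 and 0.0325, and with an estimated correlation the p were 0.239, 0.0101 and 0.239, none of which passed after adjustment over the 26 lists. At the preset correlation, 83 of 100 splits of the libraries gave at least as many passing lists. The limma test fry, which asks whether a list moves one way and not whether it differs from other genes, passed for glycolysis alone (adjusted p = 0.0402). CYC1 and NDUFA4 of the respiratory chain were at 0.64 and 0.46 and NDUFA5 at -0.86. The glycolytic enzymes GPI, PFKP and ALDOC were at 0.46, 0.44 and 0.51, and MSH6, FANCI and RBBP8 of DNA repair at -1.35, -0.82 and -1.42. No member of these lists passed in limma over all genes or adjusted over the list alone (0 of 75, 0 of 19 and 0 of 21). With the repeat number as a block the DNA repair call ended (limma camera adjusted p = 0.0728), while the cytosolic (0.0199) and mitochondrial (0.0279) ribosomal protein lists then passed, both higher. Without the block the limma camera p of these lists with an estimated correlation were 0.596 and 0.170. With quantile normalization the calls of oxidative phosphorylation (limma camera adjusted p = 0.357) and glycolysis (0.380) ended, and translation factors, heat shock chaperones and G2 and M phase genes passed, all lower, each with 0.00983. Their medians were then -0.22, -0.22 and -0.43, against 0.02, 0.03 and -0.44 without that normalization, where their limma camera p with an estimated correlation were 0.375, 0.289 and 0.357. Without that normalization the G2 and M phase list also passed, lower, among genes with a mean FPKM of at least 5 (limma camera adjusted p = 0.0173). In tests chosen after the data were seen, it passed with repeats 2 and 3 averaged (0.0229) and with a term for repeat 1 (0.0348).

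In control cells, EGFR, CCNA2 and VEGFA were higher in polysome RNA than in input RNA by 1.07, 1.24 and 1.28 on the log2 scale on average, and METTL1 by 0.05. In repeat 1 these differences were 0.01, 0.24 and -0.09 for EGFR, CCNA2 and VEGFA, and in repeats 2 and 3 they lay between 1.53 and 2.04. The smallest p belonged to PELI2 (1.06), CLMN (0.86), RNF168 (0.65), HNRNPH2 (0.92) and TRIM38 (0.61), none past the threshold, each with a limma adjusted p of 0.232. Over all 12 libraries limma called 0 of 8074 genes, with 1735 at an unadjusted p below 0.05, 0 over the 6 control libraries alone, with 1400, and 0 with the repeat number as a block, with 4126. Without control input replicate 1 it called 3945, of which 3149 were higher in polysome RNA. With repeats 2 and 3 averaged as 1 sample, limma called 0 genes, with 2 at an unadjusted p below 0.05. Over the control libraries alone, so averaged, it called 0, with 4. Groups did not overlap in 21.7% of the genes, where chance gives 10%. Shifting each library to an equal median moved all of these differences by -0.55, and METTL1 was then at -0.50, while it was at -0.24 with quantile normalization and at -0.04 without control input replicate 3. RNF168 was at -0.0040 with quantile normalization.

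In the mouse liver tumors, 3' fragments of tRNAs carrying alanine, tyrosine and valine rose most after NaBH4 treatment among the tRNAs of the fixed m7G list. The median log2 rise over isodecoders was 4.04 ± 0.262 for Tyr-GTA, 3.86 ± 0.134 for Ala-CGC, 3.46 ± 0.219 for Val-TAC, 3.37 ± 0.305 for Ala-AGC and 3.10 ± 0.240 for Ala-TGC (SD, n = 3 mice). Outside the list, Ile-TAT rose by 4.51 ± 0.193 and the initiator tRNA iMet-CAT by 3.65 ± 0.184. Other families of the list had values near 0, with 0.02 ± 0.160 for Arg-ACG, 0.08 ± 0.0793 for Arg-TCT, 0.01 ± 0.0726 for Met-CAT, -0.26 ± 0.232 for Cys-GCA and -0.26 ± 0.288 for Phe-GAA. The share of 3' fragments among mature tRNA reads was 40.2%, 40.1% and 48.9% in the inputs and 66.0%, 63.0% and 65.2% after treatment.

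**Figure D2:**
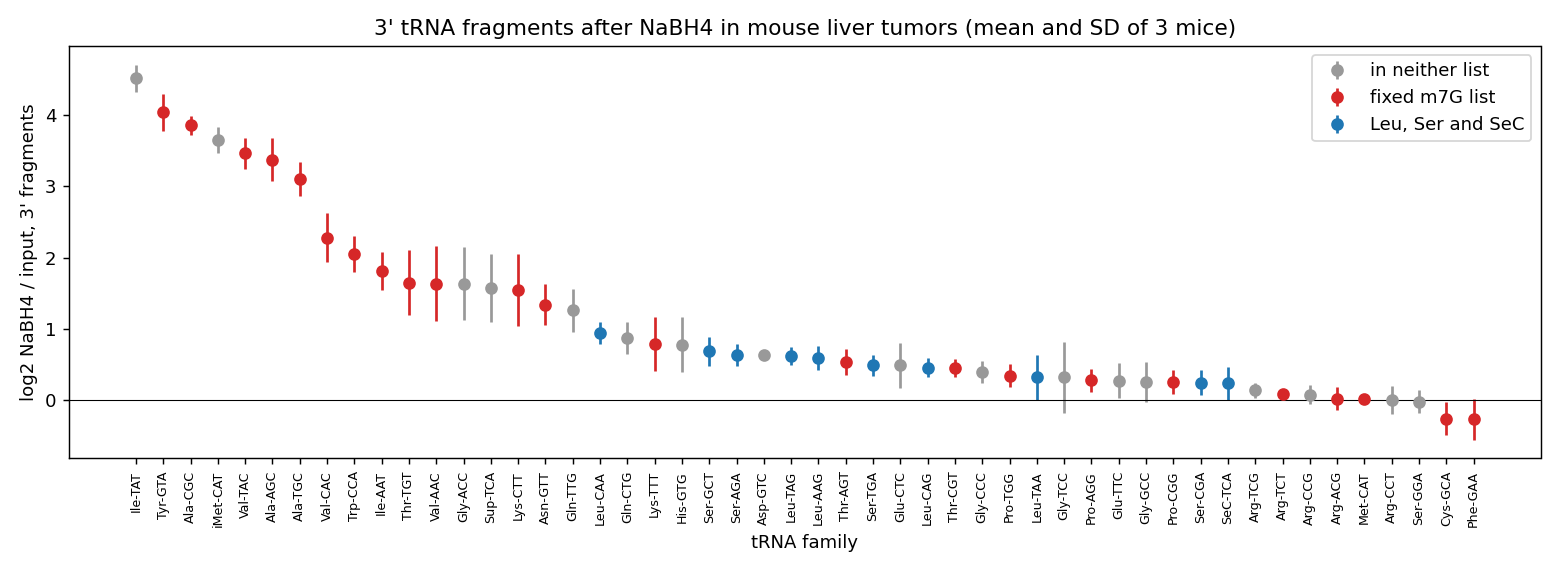
Median log2 ratio of NaBH4-treated over input 3' tRNA fragments per tRNA family in mouse liver tumors, with points for the mean and bars for the SD of 3 mice; red families are in the fixed m7G list, blue ones are Leu, Ser and SeC, and grey ones are in neither. The highest families were Ile-TAT at 4.51 and Tyr-GTA at 4.04, and the lowest were Cys-GCA and Phe-GAA at -0.26.

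Of 16849 features tested, limma called 30, all higher after treatment, of which 29 were 3' fragments and 1 was a precursor fragment of Tyr-GTA. The 25 called isodecoders of the m7G list, out of 108, were 15 of alanine, 4 of tyrosine, 4 of valine and 1 each of lysine and tryptophan, and 58 passed adjusted over the list alone. The 4 called outside the list were 2 of Ile-TAT and 2 of iMet-CAT. The largest rises past the threshold were those of Ala-CGC-4 (5.24), Ala-TGC-5 (5.08), Ile-TAT-2 (4.57), Ile-TAT-1 (4.45) and Tyr-GTA-2 (4.38), with limma adjusted p from 0.000837 to 0.0277. Ala-CGC-4 and Ala-TGC-5 were given the same treated values, 484, 256 and 157, and Ala-TGC-2 and Ala-TGC-3 had the same log2 difference, so isodecoders with near-identical sequence are not independent and their values are uncertain. Tyr-GTA-2 went from 3357, 2799 and 3010 to 74594, 50545 and 68471 in the deposited units. With the mouse as a block limma called 315 features, 260 higher and 55 lower. Of the higher, 141 were features other than tRNAs and 101 were 3' fragments, and of the lower 19 were features other than tRNAs, 18 were 5' fragments and 16 were whole tRNAs. Without the intensity trend limma called 0 features, with 583 at an unadjusted p below 0.05, while edgeR on recovered reads called 16, all 3' fragments. Leaving out 1 input library gave 14, 4 and 17 calls for mouse 1, 2 and 3, and leaving out 1 treated library gave 6, 8 and 28.

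Over whole lists, the median isodecoder of the m7G list was higher after treatment by 1.27 ± 0.357 (SD, n = 3 mice), that of Leu, Ser and SeC tRNAs, which have a long variable loop and served as the comparison, by 0.62 ± 0.148, and that of tRNAs in neither list by 0.53 ± 0.129. The m7G list exceeded the Leu, Ser and SeC list by 1.01, 0.71 and 0.23 in the 3 mice, a mean of 0.65 ± 0.392, and by a mean of 0.41 without the filter on low values. The two-sided exact sign-flip permutation test gave p = 0.25 with n = 3, which is the smallest p this design allows. In the m7G list 79 of 108 isodecoders were higher in all 3 mice, in the Leu, Ser and SeC list 26 of 28, and in neither list 33 of 47. None of the 28 Leu, Ser and SeC isodecoders passed in limma without a block (0 calls, 0 adjusted over the list alone), and none in edgeR (0 calls). With the mouse as a block, limma called 18 of these 28 higher, 63 of the 108 of the m7G list and 20 of the 47 in neither list. Small RNA lists held 0 called members in limma. The median log2 difference over the measured members was -0.16 ± 0.117 (SD, n = 3 mice) for 6 of 7 hepatocyte microRNAs, -0.31 ± 0.117 for 11 of 12 of the let-7 family, -0.30 ± 0.382 for 9 of 16 tumor-associated and -0.36 ± 0.317 for 3 of 6 hematopoietic microRNAs, and 0.50 ± 0.0526 for 8 of 16 Y, vault, 7SK, 7SL, RNase MRP and RNase P RNAs. Of 7 endothelial and stromal microRNAs only Mir143 was measured, at 0.32 ± 0.657.

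In SNU449 cells the median 3' fragment of the m7G list was higher after NaBH4 treatment in both control and METTL1-overexpressing cells. There was 1 library per condition, so the values describe these libraries and have no replicate check. The median log2 ratio over 147 isodecoders was 1.12 in control cells (95% counting interval 1.07 to 1.19) and 1.17 with overexpression (1.14 to 1.34). Both lay at the percentile 100 of 10000 random lists matched on level. The random lists were drawn from all 227 isodecoders, which include the 147, so the percentiles of the lists depend on one another. The 36 Leu, Ser and SeC isodecoders were at 0.64 and 0.76, at the percentiles 11.7 and 14.3, and the 44 in neither list at 0.52 and 0.46, at the percentiles 4.63 and 0.69. In control and overexpressing cells 112 and 123 of the 147 isodecoders of the m7G list were higher after treatment. So were all 36 of Leu, Ser and SeC in both, and 36 and 39 of the 44 in neither list. Ile-TAT had family medians of 6.29 and 6.42, iMet-CAT of 4.64 and 4.19, Val-TAC of 3.90 and 4.13, Asn-GTT of 3.33 and 3.27, and Cys-GCA of -1.13 and -0.71. The share of 3' fragments was 55.1% in control input (95% Wilson interval 55.0 to 55.1) and 72.5% after treatment (72.5 to 72.6), and with overexpression 59.7% (59.6 to 59.7) and 73.7% (73.7 to 73.8).

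METTL1 was listed at 4.20 in the input and at 0 in the treated library of control cells, and at 126 and 96.4 in those of overexpressing cells, in the deposited units. WDR4 was at 16.1 and 9.61 in control cells and at 19.5 and 8.33 in overexpressing cells. In these units 1 read was worth 0.700 and 0.874 in the input and treated libraries of control cells, and 0.885 and 1.19 in those of overexpressing cells. These are fragments in small RNA libraries, so they do not give the mRNA level of METTL1 or WDR4. With overexpression the ratio of the m7G list was higher by a median of 0.17 (95% counting interval 0.12 to 0.18; percentile 97.9), that of Leu, Ser and SeC tRNAs by 0.15 (percentile 46.5) and that of tRNAs in neither list by 0.01 (percentile 1.40). The medians of the m7G list and of Leu, Ser and SeC tRNAs were close, although their percentiles differed. Among families, picked after their values were seen, the median change of the ratio was 0.52 for Gly-TCC, 0.48 for Val-CAC, 0.48 for Val-AAC and 0.44 for Ala-AGC, and -0.45 for Tyr-GTA and -0.44 for iMet-CAT. In input RNA, 3' fragments of the m7G list were higher by 0.12 (percentile 79.4) and those of Leu, Ser and SeC tRNAs by 0.15 (percentile 73.8), and those in neither list by 0.07 (percentile 10.95). Among the 40 largest differences picked by size, 39 involved a library listed at 0. HULC had 0 and 243 reads in control input and treated RNA and 159 and 83 with overexpression, and JPX had 8, 209, 464 and 0 reads in the same order. The exception, Ile-TAT-1, went from 78 to 5063 reads in control cells and from 41 to 3043 with overexpression.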

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

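The 3 tests of the input libraries of repeat 1 in this part were chosen only after the result was seen.

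Among the genes named by the rule, 6 had a knockdown difference in polysome RNA of the opposite sign to that in input RNA in all 3 repeats. Of all 8074 genes, 441 were lower in polysome and higher in input RNA in all 3 repeats and 313 the reverse. The 6 were not a larger share of the genes named by the rule than these were of all genes. PAK1IP1, TRMT10C and CYC1 were named at least in part for their polysome minus input difference, which favours opposite signs. PAK1IP1, a ribosome biogenesis factor, was at -1.04 in polysome and 0.65 in input RNA, and TRMT10C, of mitochondrial RNase P, at -1.08 and 0.74. TRMT6, a subunit of the tRNA m1A methyltransferase, was at -0.78 and 0.27, and BIRC3, an inhibitor of apoptosis, at -0.47 and 0.34. The glycolytic enzyme ALDOA was at 0.14 and -0.43 and CYC1, of respiratory complex III, at 0.27 and -0.37. The polysome minus input differences were -1.69, -1.83, -1.05, -0.81, 0.57 and 0.64 in the order named. None passed the limma interaction test over all 12 libraries, with adjusted p of 0.841 for PAK1IP1 and TRMT10C and 0.977 for the other 4.

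Reads of partly processed tRNA precursors in the mouse tumors, outside the comparison of mature tRNAs, were higher after NaBH4 treatment than in the input by a log2 of 0.80 ± 0.133 (SD, n = 3 mice), in 3 of 3 mice, from 5841 to 10776 reads per library. These are summed reads: over the 254 features tested the median was 0.32, and limma called 1, a precursor fragment of Tyr-GTA.

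The input libraries of repeat 1 stood apart from those of repeats 2 and 3, which bears on every polysome minus input difference. Across genes, the input knockdown difference of repeat 1 correlated with those of repeats 2 and 3 at r = -0.02 and 0.02. With the polysome differences of repeats 1, 2 and 3 it correlated at r = 0.53, 0.48 and 0.47. Averages over the 3 repeats in input RNA and translation efficiency therefore mix unlike differences. An exchange of input and polysome labels in repeat 1 would by itself need a repeat 1 polysome library that resembles input RNA. Across genes the repeat 1 polysome libraries correlated more with the polysome than with the input libraries of repeats 2 and 3, by at least 0.104. The r were 0.967 against 0.823 in control and 0.944 against 0.840 in knockdown cells. This test cannot exclude an exchange if both repeat 1 libraries of an arm resemble polysome RNA. They correlated with each other at r = 0.992 in control and 0.972 in knockdown cells. A batch difference stays open: the SD between repeats 1 and 2 exceeded that between repeats 2 and 3 by at least 4.38 times in each group. Polysome-like RNA in the repeat 1 input also stays open and may be the cause, since that input correlated more with the polysome than with the input libraries of repeats 2 and 3 (r = 0.970 against 0.834 in control and 0.953 against 0.826 in knockdown cells), by at least 0.126. No biological explanation was tested.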

How the results depend on the processing

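The tests with a term for repeat 1, with repeats 2 and 3 alone or averaged, with the polysome or input libraries alone combined with a block or quantile normalization, and with edgeR, the list tests with the polysome or input libraries alone, and the m7G list difference without each mouse were chosen after the data were seen. In the named genes, 2278 of 2638 combinations of 104 gene results and settings kept direction and side of the threshold, 337 newly passed it and 23 changed sign.

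In polysome RNA limma called 1117 genes with the polysome libraries alone, 902 there with quantile normalization, 3392 there with a replicate block, 1 with a replicate block over all libraries, 4260 with a term for repeat 1 and 5209 in repeats 2 and 3 alone. Leaving out 1 library gave 0 to 4, the 4 without control input replicate 1. In input RNA it called 1 with a replicate block, 1 with the input libraries alone and a block, 486 with a term for repeat 1 and 4092 in repeats 2 and 3 alone. For translation efficiency these last settings gave 3434 and 5410, and leaving out 1 library 0 to 3, with 3 without control input replicate 1 and 1 without knockdown input replicate 1. For polysome against input RNA of control cells they gave 6426 and 7111, and leaving out 1 library 0 to 3945, the 3945 without control input replicate 1. Where repeats 2 and 3 share a preparation, as their closeness leaves open, the spread is too small and these counts too high, and the cause was not tested. With repeats 2 and 3 averaged as 1 sample, limma called 0 genes in every one of these comparisons, with fewer samples in each group. The block changed no other call of a gene or list than those given here or in the report.

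Of the gene lists, 7 passed in polysome RNA with quantile normalization, all lower, and over all 12 libraries 0 with an estimated correlation and 0 in fry. With the polysome libraries alone 9 of 26 passed in fry, angiogenesis and hypoxia, apoptosis, DNA repair, ER chaperones, growth factor receptor signalling, heat shock and oxidative stress lower and glycolysis and hepatocyte genes higher, with limma adjusted p from 0.00314 to 0.0298, and 0 with an estimated correlation. In input RNA 1 passed with quantile normalization, 4 with a term for repeat 1, 4 with repeats 2 and 3 averaged, 0 with an estimated correlation and 0 in fry. In translation efficiency 5 passed with a term for repeat 1. Without that term 0 passed with an estimated correlation and 1 in fry. With the term further lists passed in fry, among them apoptosis (limma fry adjusted p = 0.00190), migration (0.00591) and glycolysis (0.0138). The cause was not tested.

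In the mouse comparison limma called 13 features with median scaling, 0 without the intensity trend and 315 with a replicate block, edgeR 16, 13 with TMM and 299 with a replicate block, and leaving out 1 library gave 4 to 28: without input 1, 2 and 3, 14, 4 and 17, and without the treated library 1, 2 and 3, 6, 8 and 28. The m7G list exceeded the Leu, Ser and SeC list by 0.47 to 0.86 when 1 mouse was left out, and by 0.41 without the filter. In SNU449 cells the ratio with overexpression was 1.07 over isodecoders with at least 10 in every library, and with median scaling the change with overexpression was 0.20 in the ratio and 0.0740 in input; the cause was not tested.

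Signs changed as follows. Leaving out 1 library leaves its pair incomplete, and for the other settings the cause was not tested. METTL1 in translation efficiency was at -0.00233 with repeats 2 and 3 averaged and at -0.15 to 0.61 when 1 library was left out, and VEGFA at 0.0533 with quantile normalization and at -1.01 to 0.55. Median scaling moved every gene of polysome against input RNA by -0.55 and so put METTL1 at -0.50, which says nothing about this gene. METTL1 there was at -0.24 with quantile normalization of all or of the control libraries, and -0.0367 to 0.16 when 1 library was left out, and RNF168 at -0.00400 and -0.00419 with those quantile normalizations. When 1 library was left out in input RNA, WDR4 ranged from -0.51 to 0.10, CCNA2 from -0.18 to 0.94, EGFR from -0.73 to 0.21, VEGFA from -0.98 to 0.57 and RPSA from -0.0248 to 0.71. The planned test of codons read by m7G tRNAs was not run. The FPKM table gives no depth, and the low recovery of simulated changes limits what a count of 0 shows.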

Other observations

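The tests of genomic span and of iMet and Ile-TAT in this part, and the splits for gene counts in the MHCC97H comparisons, were chosen only after the result was seen, while the splits for gene lists and for the mouse features were not.

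Translation factors were among the groups with several lower members in polysome RNA of knockdown cells when the 6 polysome libraries were fitted alone. In that fit 1029 of all 8074 genes were called lower and 88 higher. The counts of list members given here were not tested against those shares. Of 44 translation factors, 9 fell in limma over all genes and 10 adjusted over the list alone, among them EIF5, which acts in start codon selection, by 0.88 on the log2 scale (limma adjusted p = 0.0178). Growth factor receptor signalling had 6 falls and 1 rise among 28 genes, and DUSP6, a phosphatase of ERK, was at -0.79 without passing (limma adjusted p = 0.0543). Among heat shock chaperones 5 of 16 fell and 1 rose, with HSPD1, the mitochondrial chaperonin, at 415 ± 19.5 FPKM in control and 199 ± 17.2 FPKM in knockdown cells (SD, n = 3 each) and HSPA4 at -1.25. The others were CHORDC1, HSP90AA1 and HSPH1, which fell, and HSPB1, which rose. Of 20 ER chaperone genes 4 fell, EDEM1, HSP90B1, PDIA6 and SEL1L, and 8 adjusted over the list alone. The angiogenesis and hypoxia list had 5 falls among 14 genes, BNIP3L, EGLN1, HIF1A, P4HA1 and PDK1. Of the oxidative stress list 4 of 20 fell, with GCLM of glutathione synthesis at -0.82 and ME1, a source of NADPH, at -1.34, beside ABCC2 and GCLC. Of the 29 other RNA modification genes listed as RNA methyltransferases, 7 passed adjusted over the list alone, in both directions. TRMT6 fell by 0.78 and TRMT10C by 1.08, and CTU2, of tRNA thiolation, rose by 0.50. Of 31 G2 and M phase genes 5 fell, ANLN, BUB1, BUB1B, ECT2 and NUSAP1, and ECT2, a regulator of cytokinesis, was at 15.7 ± 0.685 FPKM in control and 4.43 ± 0.348 FPKM in knockdown cells. The lists of fatty acid synthesis and of G1 and S phase had 3 falls each, with SCD at -0.69 and CDK6 at -0.83. CDH2, a cadherin of the migration list, fell by 1.004, and among p53 targets 2 fell and 1 rose, BAX at 0.57. The other falls were FADS1 and ME1 of fatty acid synthesis, CCNA2 and MCM6 of G1 and S phase, and CCNG1 and RRM2B of the p53 targets. CTU2 and the members named here without a value were picked after their values were seen.

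Without quantile normalization, none of these lists passed in limma camera with a preset correlation over all 12 libraries, except the G2 and M phase list among genes with a mean FPKM of at least 5 (adjusted p = 0.0352) and, chosen after the data were seen, with repeats 2 and 3 averaged (0.0298). With quantile normalization, translation factors (limma camera adjusted p = 0.00333), ER chaperones (0.0123), oxidative stress (0.0123), heat shock (0.0150), fatty acid synthesis (0.0328) and the G2 and M phase list (0.0113) passed, all lower. Without it, the limma camera adjusted p were 0.359 for translation factors (p = 0.359 with an estimated correlation), 0.654 for growth factor receptor signalling (p = 0.776), 0.448 for heat shock (p = 0.445), 0.198 for ER chaperones (p = 0.506), 0.448 for angiogenesis and hypoxia (p = 0.715), 0.448 for apoptosis (p = 0.550) and 0.477 for oxidative stress (p = 0.465). In limma camera the adjusted p were 0.448 for RNA methyltransferases (p = 0.283 with an estimated correlation), 0.276 for fatty acid synthesis (p = 0.194), 0.574 for G1 and S phase (p = 0.769), 0.448 for migration (p = 0.401) and 0.654 for p53 targets (p = 0.637), whose median of -0.29 had the opposite sign to the test. The same held for cholesterol synthesis (median -0.06, limma camera adjusted p = 0.704), immediate early genes (-0.00, 0.704), inflammatory genes of NFkB (-0.11, 0.750) and PI3K, AKT and mTOR (-0.02, 0.718). Glycolysis (0.276), hepatocyte genes (0.297), the integrated stress response (0.448), interferon-stimulated genes (0.705), mitochondrial ribosomal proteins (0.266) and the proteasome (0.982) did not pass either in limma camera.

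The knockdown difference in polysome RNA was lower for genes of longer genomic span, and no biological explanation was tested. A batch confined to repeat 1 was excluded, since the difference of repeat 1 correlated with that of repeats 2 and 3 across genes (r = 0.732). A gene length bias stays open, as does a difference in preparation between control and knockdown libraries in every repeat. The Spearman correlation with span was -0.41, -0.41 and -0.42 in the polysome repeats, against -0.31, 0.23 and 0.21 in the input repeats. Genomic span includes introns and is not transcript length, which was not examined. Without the span trend 464 of 1123 calls were kept among 602, and without the span and level trends 392 among 492, while the median of the genes first called lower moved from -0.83 (SD 0.26) to -0.60 (SD 0.29) and -0.57 (SD 0.29) and that of the genes first called higher from 0.58 to 0.59 and 0.56. The medians of the ribosomal protein, oxidative phosphorylation and DNA repair lists moved from 0.42, 0.29 and -0.46 to 0.25, 0.22 and -0.16 without the span trend and to 0.04, 0.08 and -0.16 without both. That of the G2 and M phase list moved less, from -0.40 to -0.32 without the span trend and to -0.37 without both.

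The 3' fragments of iMet and Ile-TAT rose after NaBH4 treatment though neither is in the m7G list. Reads shared with the Met-CAT or Ile-AAT family do not account for the rise. In family medians iMet exceeded Met-CAT, and Ile-TAT exceeded Ile-AAT, by at least 2.60 in all pairs of libraries. Reads shared with other listed tRNAs or with a single isodecoder were not examined. Few reads were excluded, with a lowest counting limit of 3.38. A rise of the size seen in the Leu, Ser and SeC isodecoders does not account for these rises. In all pairs of libraries iMet and Ile-TAT exceeded the median of those isodecoders by at least 2.95. Both families were picked after their rises were seen, so this comparison is not independent of that choice. Those isodecoders had an SD of at most 0.73. Of single isodecoders, Leu-CAA-5 lay above iMet in overexpressing SNU449 cells, from 2 input reads. No biological explanation was tested.

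The knockdown difference had the same sign in all 3 repeats in 68.9% of the genes in polysome RNA, 38.6% in input RNA and 71.2% in translation efficiency. Chance gives 25% where the repeats are independent and 50% where repeats 2 and 3 are copies of one another.

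For gene counts over all libraries the real count was 0, which every split reaches, so these splits say nothing about chance. All 10 splits of the libraries did so in the polysome comparison, 10 in the input comparison and 10 in polysome against input RNA, with 0 as the highest other. With the polysome libraries alone the real split gave 1117 and the highest other 0, and 10 splits are too few for a share under 0.05. For translation efficiency all 100 splits drawn did so, and the highest other gave 1455. That split kept the control polysome libraries together and mixed only the input libraries, so it is not free of the knockdown difference. Among the 12 splits that parted same-numbered libraries, the highest other was 2. For lists, 8 of 10 splits, the real one among them, gave at least the real 3 in polysome RNA (highest other 8). In input RNA 9 of 10, the real one among them, gave at least the real 2 (highest other 5). The numbers of lists that passed there therefore did not stand out from other groupings of the same libraries. In translation efficiency 83 of 100 gave as many as 3 (highest other 9), so chance is not excluded. In the mice 1 of 10 splits, the real one with 30, reached that count, the highest other gave 1, and 10 splits are too few for a share under 0.05.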
